A study of Mus musculus with 4 samples.

How the data were processed

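RNA from isolated ear Langerhans cells of wild-type mice was measured in 4 libraries, 2 from ears treated with Vaseline and 2 from ears treated with imiquimod. Per the labels' protocols, RNA was extracted with a Zymo DirectZol MicroPrep kit, and 10 to 70 ng of total RNA went into each library, made with the SMARTer Stranded Total RNA-Seq Pico Input kit, version 2. Per the submitters' processing notes, Trimmomatic, HISAT2, SAMtools and StringTie were used on the mouse build GRCm38; no versions, annotation release, strand setting or treatment of multi-mapped reads are stated. The deposited values are counts per gene, whole numbers with no scaling to depth. The count table held 55487 Ensembl genes, of which 55227 matched GENCODE release vM21 and 3598 had no count in any library; 234 shared a symbol with another and none lacked a symbol, so leaving out genes without a symbol would move nothing and was not run. Each gene was tested as deposited.

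Library totals were 41998172 and 76028955 counts for Vaseline 1 and 2 and 14902782 and 20690182 for imiquimod 1 and 2, a 5.10-fold range. The spread between libraries of a group far exceeded counting error: chi-square per degree of freedom was 95.1 in Vaseline and 88.1 in imiquimod. The common dispersion was 0.369, a biological coefficient of variation of 0.607.

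Groups were compared with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3; TMM factors, two-sided) and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p threshold of 0.05. The edgeR filter filterByExpr with its defaults (minimum count 10, minimum total 15) kept 39439 genes and left out 16048. Levels are TMM-normalised CPM (counts scaled to the effective library total), as mean ± SD over 2 libraries; fold changes are log2 of imiquimod over Vaseline with a standard error (SE) taken as the fold change over the square root of the F statistic. Where every library of a group had a count of 0, the fold was bounded with a floor of 3 counts per library. Floors cover counting error alone, since PCR reads without molecular identifiers are not independent molecules.

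Before the data were examined, 39 gene lists with 888 symbols were written, covering Langerhans cell functions, RNA quality and markers of other cell types. Of these symbols, 875 were found, 13 of them under a synonym, and 866 list memberships were tested. Lists were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated from the data, and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Members were counted at adjusted p under 0.05 over all genes and adjusted over the list alone. Named genes were fixed by a rule: Cd274, Cd207, Il23a, Tlr7, Hal and Htr2a; in each direction, up to 12 genes of smallest p with adjusted p under 0.05, absolute log2 fold change of at least 1, groups that do not overlap, mean CPM of at least 5 and a symbol that is not a model name; and up to 4 members of smallest p per list. Of genes past the threshold, 11 higher and 38 lower met the second part of this rule. Some genes that met the rule are not reported here.

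A background of reads spread over genes at low level was estimated in each library after the data were seen, as the median count per exonic kilobase over 1768 olfactory and vomeronasal receptor genes, with exon unions from GENCODE vM21. In each library the ratio of a gene's level to the background was taken. Genes whose mean ratio over the 4 libraries was at least 5 were refitted alone. The bound was met by 15008 genes, of which 14602 passed the filter. This set is called genes above background. The mean ratio gives most weight to libraries with a low background, such as Vaseline 2. Genes high only in imiquimod 2, where the background was highest, may thus fall below the bound, as Mmp8 did at 4.36. The share of each gene's exonic bases that exons of other genes cover on either strand was computed with bedtools 2.31.1. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

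The fit was tested on simulated data with the same means and totals and the dispersions of the fit to all tested genes, in which 200 genes were changed. The simulated counts were drawn independently and held no background that differs between libraries. At 2-, 4- and 8-fold, it recovered 0%, 1.54% and 15.6% of changed genes among all tested genes, and 1.49%, 10.6% and 66.7% among genes above background; 0 and 4 unchanged genes were called.

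Other settings, fixed before the data were examined, were RLE, upper-quartile and no normalization factors, DESeq2 1.42.0, limma-voom, the older and the robust quasi-likelihood forms, no filter and a stricter filter (at least 10 counts per library and 50 in total), summing genes that share a symbol, leaving out marker genes of other cell types, a block for the replicate number, leaving out each library in turn, an adjusted p threshold of 0.1 and a minimum fold of 1.5. Settings chosen after seeing the data were protein-coding genes only, genes above background at 5 and at 10 times with edgeR, DESeq2 and limma-voom, subtraction of the background, and a block that crosses the replicate numbers. With a library left out, the lone library of its group is assumed to vary like the other group. No sample was left out of the main comparison.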

Results

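The study measured the transcriptome of Langerhans cells, the dendritic cells of the epidermis, isolated from mouse ears after Vaseline or imiquimod, a Toll-like receptor 7 agonist whose topical use gives a psoriasis-like inflammation. Each treatment had 2 libraries of total RNA. All mice were wild type. Library totals were 41998172 and 76028955 counts for Vaseline 1 and 2 and 14902782 and 20690182 for imiquimod 1 and 2. The labels do not say whether the libraries of a group came from separate animals, so p-values reflect the spread between these samples, which may be technical in part. The sample descriptions give both Vaseline libraries 1 letter code and each imiquimod library a code of its own. Their meaning is not stated, and if they mark batches, batch and treatment cannot be separated here.

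The comparison asks how Langerhans cells of imiquimod-treated ears differ from those of control ears; the series title names PD-L1, cis-urocanic acid and gamma delta T cells that make IL-17. Lcn2, which binds bacterial siderophores, had a normalised level of 3.09 ± 1.33 CPM with Vaseline and 34.5 ± 22.1 with imiquimod (SD, n = 2 each), a log2 fold change of 3.49. S100a8, a subunit of calprotectin, went from 5.0 ± 5.98 to 32.1 ± 22.6 CPM (SD, n = 2 each). Both are also markers of neutrophils, and Lcn2 of activated keratinocytes. Mmp9, a gelatinase, was lower, at 131 ± 35.8 CPM with Vaseline and 10.8 ± 2.66 with imiquimod (SD, n = 2 each), and so was Clec4f, a C-type lectin, at 48.4 ± 21.1 and 5.34 ± 0.50 CPM. The mitotic genes Ccnb2, a cyclin, and Bub1, a spindle checkpoint kinase, were lower by log2 fold changes of -2.65 and -2.75.

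With the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, 25 genes were higher and 54 lower with imiquimod among 39439 tested. The split depended on the scaling: it was 17 and 14 with RLE factors, 41 and 56 with upper-quartile factors and 8 and 5 on library totals alone. The median log2 fold change of all tested genes was 0.41, and 0.16, 0.76 and 1.30 under those scalings and 0.15 with DESeq2. It mixes genes at no more than 2 times the background (median 1.13) with genes at 5 times or more (-0.68). It therefore does not mark a level of no change. Fold changes below are given as fitted and depend on the scaling. The counts rested on single libraries: they were 2959 higher and 317 lower without Vaseline 1, 28 and 17 without Vaseline 2, 15 and 6 without imiquimod 1, and 8 and 0 without imiquimod 2. Of the 25 genes higher, 16 were protein-coding, and of the 54 lower, 44.

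Reads at genes with little known use in skin differed between libraries. Olfactory and vomeronasal receptor genes, chemosensory genes of the nose, had median levels of 0.377 and 0.0913 CPM per exonic kilobase in Vaseline 1 and 2 and 0.526 and 1.26 in imiquimod 1 and 2. The group means differed 3.80-fold and the Vaseline libraries 4.13-fold. Among 14706 genes at no more than 2 times this background, 92.2% had a positive log2 fold change, with a median of 1.13. Among 14605 genes at 5 times or more, the median was -0.68, or 0.13 when scaled to library totals, and 17.1% had a positive value. Of the 25 genes higher, 15 lay under 5 times the background, and of the 54 lower, 2 did. That split may follow in part from the measure, a mean of ratios that gives most weight to Vaseline 2, where the background was lowest. Genes above background were therefore also fitted alone, a choice made after the data were seen, which brought their median log2 fold change to 0.08. In that fit edgeR called 0 genes higher and 0 lower, with 798 higher and 699 lower at an unadjusted p under 0.05. On the same genes DESeq2 called 97 higher and 156 lower, and limma-voom 0 and 0.

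**Figure D1:**
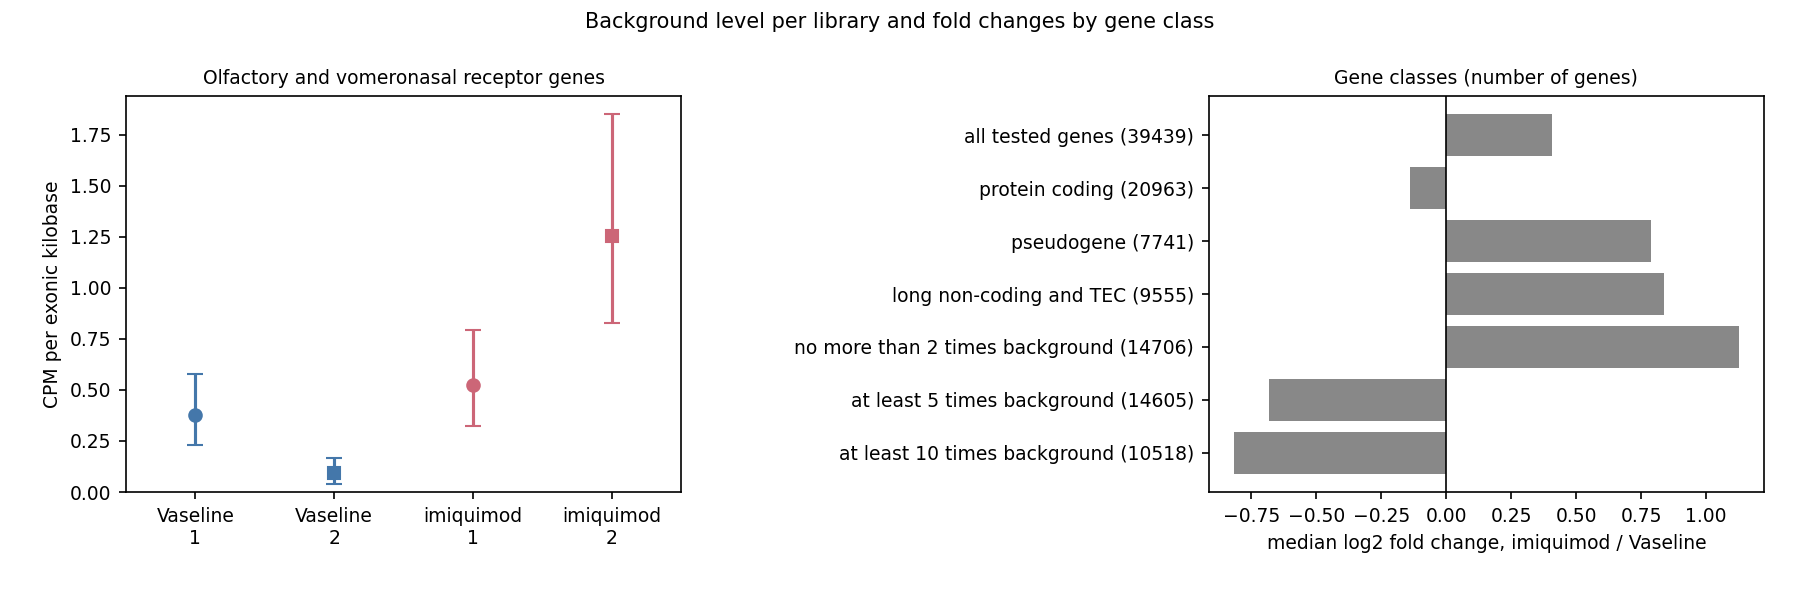
Left, level of 1768 olfactory and vomeronasal receptor genes in each library, in CPM per exonic kilobase (point, median; bar, lower to upper quartile). Right, median log2 fold change by gene class under TMM scaling, from 1.13 for genes near the background to -0.82 for genes at 10 times the background or more (-0.02 on library totals).

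Among genes named by rule as higher, Lcn2 (ENSMUSG00000026822; GRCm38 chromosome 2, 32384633 to 32388252) had an SE of 0.66 and an adjusted p of 0.000398 by edgeR quasi-likelihood. Serpina3n, a secreted protease inhibitor, had 3.29, adjusted p = 0.00113, and Saa3, an acute-phase protein, 2.65, adjusted p = 0.0365. These values are from the fit of all tested genes. Among genes above background Lcn2 and Serpina3n had 4.47 and 4.16. There they did not pass by edgeR (adjusted p = 0.312 and 0.215) but did by DESeq2. Spock2, an extracellular proteoglycan, was higher by 2.47. It had 53.3 CPM in imiquimod 1 but 7.06 in imiquimod 2, against 6.54 and 4.14 with Vaseline. Mmp8, the neutrophil collagenase, Acod1, which makes itaconate, Slfn4, and Hdc, which makes histamine, had log2 fold changes of 3.45, 3.12, 2.87 and 2.59. In Mmp8, Acod1, Slfn4 and Hdc most of the signal lay in imiquimod 2, at 21.8, 39.0, 27.0 and 40.4 CPM, against 2.75, 8.62, 3.19 and 7.67 in imiquimod 1. Commd1b had no count with Vaseline and was at least 261-fold higher with imiquimod, a bound on the mean of 30.5 CPM in imiquimod 1 and 6.25 in imiquimod 2. However, 99.9% of its exonic bases are shared with B3gnt2, so its reads cannot be placed with certainty.

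Of the 12 genes named as lower, Cyp4f37, a cytochrome P450, had the smallest p among those whose exons overlap no other gene. Cyp4f37 (ENSMUSG00000062464; chromosome 17, 32621309 to 32636184) had a log2 fold change of -3.97 (SE 0.78, adjusted p = 0.000716), with 134 ± 69.0 CPM with Vaseline and 8.51 ± 0.384 with imiquimod (SD, n = 2 each). Mmp9 (ENSMUSG00000017737; chromosome 2, 164940780 to 164955850) had -3.59 (SE 0.76, adjusted p = 0.00349), and Clec4f, whose gene lies beside that of langerin on chromosome 6, had -3.17 (SE 0.68, adjusted p = 0.00374). Ighm, the constant region of IgM, had -3.36, and Stfa3, a stefin, -3.32, though reads of stefin and cytochrome P450 genes may be shared with paralogs. Cnp, Ndufa4l2, Fam71f2 and Tspan8, a tetraspanin, had log2 fold changes of -3.15, -3.25, -3.03 and -2.94. Aarsd1 and Cracr2b, at -3.14 and -2.84, share 41.0% and 50.8% of their exonic bases with other genes, and the named Septin2 entry (ENSMUSG00000116048), at -3.53, shares 100% with a second entry for that gene, so all of these are uncertain. Among genes above background Cyp4f37, Mmp9 and Clec4f had -3.09, -2.72 and -2.30. There they did not pass by edgeR (adjusted p = 0.215, 0.312 and 0.389) but did by DESeq2. Septin2 and Cracr2b passed there by neither (DESeq2 adjusted p = 0.831 and 0.0639). Of 27 named genes past the threshold, 19 kept it without Vaseline 1, 2 without Vaseline 2, 8 without imiquimod 1 and 2 without imiquimod 2; none changed sign in any setting run.

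**Figure D2:**
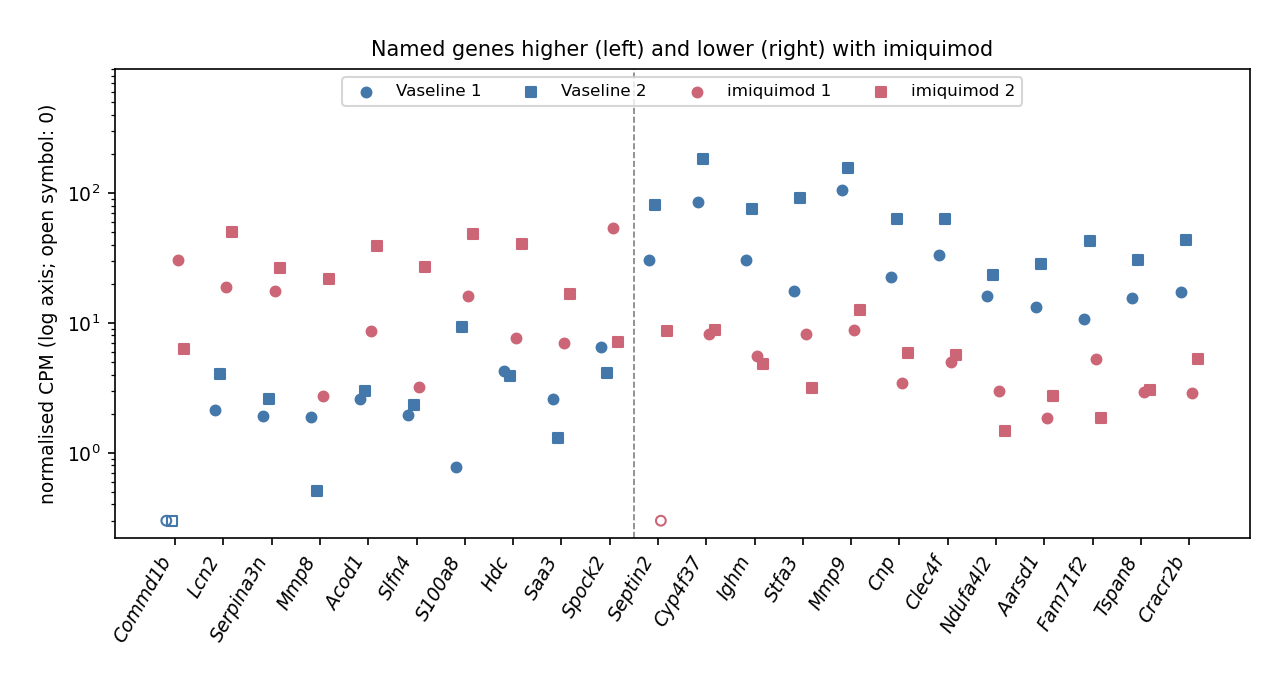
Normalised level (CPM, log axis) of genes named by rule as higher or lower with imiquimod, per library; open symbols mark a count of 0. Mmp8, Slfn4 and Hdc are far higher in imiquimod 2 (21.8, 27.0 and 40.4 CPM) than in imiquimod 1 (2.75, 3.19 and 7.67 CPM).

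Cd274, which encodes PD-L1, an inhibitory ligand for T cells (ENSMUSG00000016496; chromosome 19, 29367455 to 29388095), had 26.8 ± 18.02 CPM with Vaseline and 49.2 ± 40.4 with imiquimod (SD, n = 2 each). Its log2 fold change was 0.89 (SE 0.62, adjusted p = 0.458), smaller than the spread between replicates, with 14.1 and 39.6 CPM in the Vaseline libraries and 20.6 and 77.7 in the imiquimod libraries. Among genes above background the value was 1.95 (SE 0.78, adjusted p = 0.484), and without imiquimod 2 it was -0.38. Cd207, which encodes langerin, the lectin that defines these cells, had 4569 ± 3273 CPM with Vaseline and 888 ± 443 with imiquimod (SD, n = 2 each). Its groups did not overlap, but its log2 fold change of -2.36 (SE 1.83) did not pass, adjusted p = 0.488. Among genes above background the value was -1.57, and Cd207 passed there by DESeq2 (adjusted p = 0.0361) but not by edgeR quasi-likelihood (adjusted p = 0.489). Il23a, the IL-23 subunit that sustains IL-17 production, had 11.3 ± 8.16 and 9.82 ± 4.49 CPM, adjusted p = 0.870. Its log2 fold change was -0.18, but 0.80 among genes above background (edgeR adjusted p = 0.644). Tlr7, the receptor of imiquimod, had a log2 fold change of -0.26 at 1.85 times the background, adjusted p = 0.847. Hal, the enzyme that makes urocanic acid, had -0.50, or 0.34 among genes above background, and Htr2a, a serotonin receptor that binds cis-urocanic acid, had 0.93 at 1.08 times the background; neither passed (adjusted p = 0.637 and 0.499).

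By camera with its preset correlation, 28 of the 39 lists passed, 4 upward and 24 downward; with an estimated correlation 0 passed, and by fry 0 passed. Where a list is said below to have passed among all genes with all 4 libraries, its adjusted p with an estimated correlation was 0.604. This shared value comes from the adjustment and does not tell lists apart. The interferon-gamma response and monocyte lists, said below to pass with a library left out, had 0.927 and 0.793. Among genes above background 15 of 36 lists passed with the preset correlation, and 0 with an estimated correlation. For lists called in that fit, adjusted p values with an estimated correlation ran from 0.710 to 0.919.

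Langerhans cell and antigen presentation genes mostly had negative fold changes. Of 24 Langerhans cell identity genes, 22 had a negative log2 fold change, none passed over all genes and 4 fell when adjusted over the list alone: the macrophage marker Adgre1 (-2.15), the integrin Itgax (-2.54), Ltc4s (-1.83) and the transcription factor Spi1 (-2.12). Of all genes at 5 times the background or more, 17.1% had a positive value. The list passed downward (median -1.47, adjusted p = 1.21e-11, and adjusted p = 0.604 with an estimated correlation). Of 15 genes of MHC class II presentation, each had negative fold changes, none passed over all genes and 7 fell adjusted over the list alone, led by H2-DMa (-3.40, SE 0.89), H2-DMb2 (-3.12) and H2-DMb1 (-2.68), which load peptides onto class II molecules. Their median was -2.23, adjusted p = 2.09e-16, and adjusted p = 0.604 with an estimated correlation. Their medians among genes above background were -0.79 and -1.36, adjusted p = 5.05e-06 and 2.84e-12, and adjusted p = 0.710 for both with an estimated correlation; 0 and 3 members then fell adjusted over the list alone. Of the identity genes 6 were then positive and 16 negative, and of the class II genes 1 and 14. MHC class I presentation passed downward (20 members, none past the threshold, median -0.99, adjusted p = 5.83e-07 and 0.604 with an estimated correlation), but not among genes above background (-0.19, adjusted p = 0.129); Psmb8, an immunoproteasome subunit, had -2.09. In the same libraries mitochondrially encoded transcripts, a mark of RNA and cell quality, had a median of -1.28. The keratin gene Krt14 exceeded Cd207 in each library, so the falls of these lists need not lie within Langerhans cells.

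Of 39 interferon-stimulated genes, 29 had a positive value, where 60.6% of all tested genes did; none passed over all genes and 6 rose adjusted over the list alone. Ifit1, which binds viral RNA, had 2.16 (SE 0.64), Oasl2 2.08 (SE 0.62), Ifi27l2a 2.10 (SE 0.66) and Mx1, an antiviral GTPase, 1.78 (SE 0.64). The list passed upward (median 0.57, which is 0.16 above that of all genes; adjusted p = 0.00100), with adjusted p = 0.604 with an estimated correlation, and the preset call was lost without Vaseline 1 (adjusted p = 0.927) or imiquimod 1 (0.148). All 29 members above background had a positive fold change, 15 rose adjusted over the list alone, and the median was 0.96 (adjusted p = 3.79e-19, and 0.710 with an estimated correlation). Activated keratinocyte markers moved in the same libraries, with median levels above background (log2, relative to the mean of the libraries) of -1.23 and -0.45 in Vaseline 1 and 2 and 0.59 and 0.56 in imiquimod 1 and 2, against -0.57, -0.27, 0.44 and 0.52 for the interferon-stimulated genes. Mitochondrially encoded transcripts had a median of -1.28. Oasl2 had 8.36 and 8.43 CPM in the Vaseline libraries and 39.4 and 31.6 in the imiquimod libraries. Interferon-gamma response genes did not pass (24 members, none past the threshold, adjusted p = 0.794): the median was 0.36 while the test pointed down, and Nos2, which makes nitric oxide, had 1.65 and Ciita, the class II transactivator, -2.0. Without Vaseline 2 that list passed upward (adjusted p = 0.0478), and without Vaseline 1 downward (0.0334).

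Signalling lists depended on the genes fitted. Toll-like receptor 7 and NF-kappaB signalling passed downward (35 members, none past the threshold, median -0.61, adjusted p = 0.000859 and 0.604 with an estimated correlation), but its median was 0.25 on library totals and 0.16 among genes above background, adjusted p = 0.226. At 10 times background the list passed upward (median 0.23, adjusted p = 0.0122). Irf7, an interferon regulator, had 1.71 and the kinase Irak4 -1.26. The NLRP3 inflammasome and imiquimod off-target receptor list passed downward (14 members, median -0.80, 0.16 on library totals; adjusted p = 0.00976 and 0.604 with an estimated correlation), with 2 members falling adjusted over the list alone, Il18 (-1.80) and the adaptor Pycard (-1.72), and none over all genes; among genes above background adjusted p = 0.738. Without Vaseline 2 the preset calls of these lists were lost, at adjusted p = 0.252 and 0.144, as was the first without imiquimod 2 (0.078) and the second without imiquimod 1 (0.0508). Urocanic acid related genes did not pass (10 members, none past the threshold, median 0.75, adjusted p = 0.235), but did upward among the 5 members above background (median 0.77, adjusted p = 0.0395, and 0.710 with an estimated correlation). Their levels were -0.17 and -0.12 with Vaseline, -0.22 in imiquimod 1 and 0.32 in imiquimod 2 (log2, relative to the mean of the libraries). Uroc1, which breaks down urocanic acid, had 1.71 at 1.27 times the background.

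Of 21 chemokines none passed over all genes and 2 rose adjusted over the list alone: Ccl5 (2.15, SE 0.68) and Ccl20 (1.90, SE 0.62), which draws CCR6-bearing cells such as IL-17 producing T cells. Ccl20 had 10.3 ± 5.67 CPM with Vaseline and 38.8 ± 11.5 with imiquimod (SD, n = 2 each), while Ccl22 had -1.71. The chemokine list did not pass (median 0.23, -0.05 with RLE factors and -0.13 with DESeq2; adjusted p = 0.907), but passed upward among genes above background, with 6 members rising adjusted over the list alone (median 0.42, adjusted p = 4.72e-05, and 0.710 with an estimated correlation). Its median level above background (log2, relative to the mean of the libraries) was -0.44 and -0.09 in Vaseline 1 and 2, -0.06 in imiquimod 1 and 0.73 in imiquimod 2. Neutrophil markers (1.71) and monocyte markers (0.72) also stood highest in imiquimod 2. Of 20 cytokines that act on IL-17 producing T cells none passed; the median was 0.38 while the test pointed down, adjusted p = 0.794. This list passed upward among genes above background, with 4 members rising adjusted over the list alone (median 0.80, adjusted p = 0.00745, and 0.909 with an estimated correlation). Its levels were -0.28 and 0.19 with Vaseline, -0.24 in imiquimod 1 and 0.45 in imiquimod 2. Il1a had 1.56 and Il18 -1.80 among all genes. Il1b, chosen after its values were seen, had 105 and 347 CPM in the Vaseline libraries and 588 and 723 in the imiquimod libraries, adjusted p = 0.440.

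Dendritic cell maturation and costimulation genes passed downward (26 members, none past the threshold, median -0.58, 0.40 on library totals; adjusted p = 0.00745 and 0.604 with an estimated correlation), but had a median of 0.24 among genes above background, adjusted p = 0.916; the T cell costimulators Cd40 and Cd86 had -1.25 and -1.55. Inhibitory ligands and receptors, the list that holds Cd274, passed downward (24 members, none past the threshold, median -0.15, but 0.21 with upper-quartile factors and 0.63 on library totals; adjusted p = 0.0121 and 0.604 with an estimated correlation). They had -0.19 among genes above background, adjusted p = 0.421; Socs1, which damps cytokine signalling, had -1.46 and Tgfb1 -1.52. Both calls were lost without Vaseline 2 (adjusted p = 0.913 and 0.414) and without imiquimod 1 (0.0508 and 0.0565). C-type lectins and innate receptors did not pass (23 members, median 0.01, -0.24 with RLE factors and -0.30 with DESeq2, while the test pointed down; adjusted p = 0.474); adjusted over the list alone 3 rose, among them Clec4e (1.79), and 2 fell, Clec4n (-1.94) and Clec7a (-2.39), a receptor for fungal glucan. Cell migration and tissue exit genes passed downward (25 members, Mmp9 past the threshold over all genes and 2 adjusted over the list alone, median -0.73, 0.10 on library totals; adjusted p = 0.000394 and 0.604 with an estimated correlation), and had -0.11 among genes above background, adjusted p = 0.0485 and 0.813 with an estimated correlation.

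**Figure D3:**
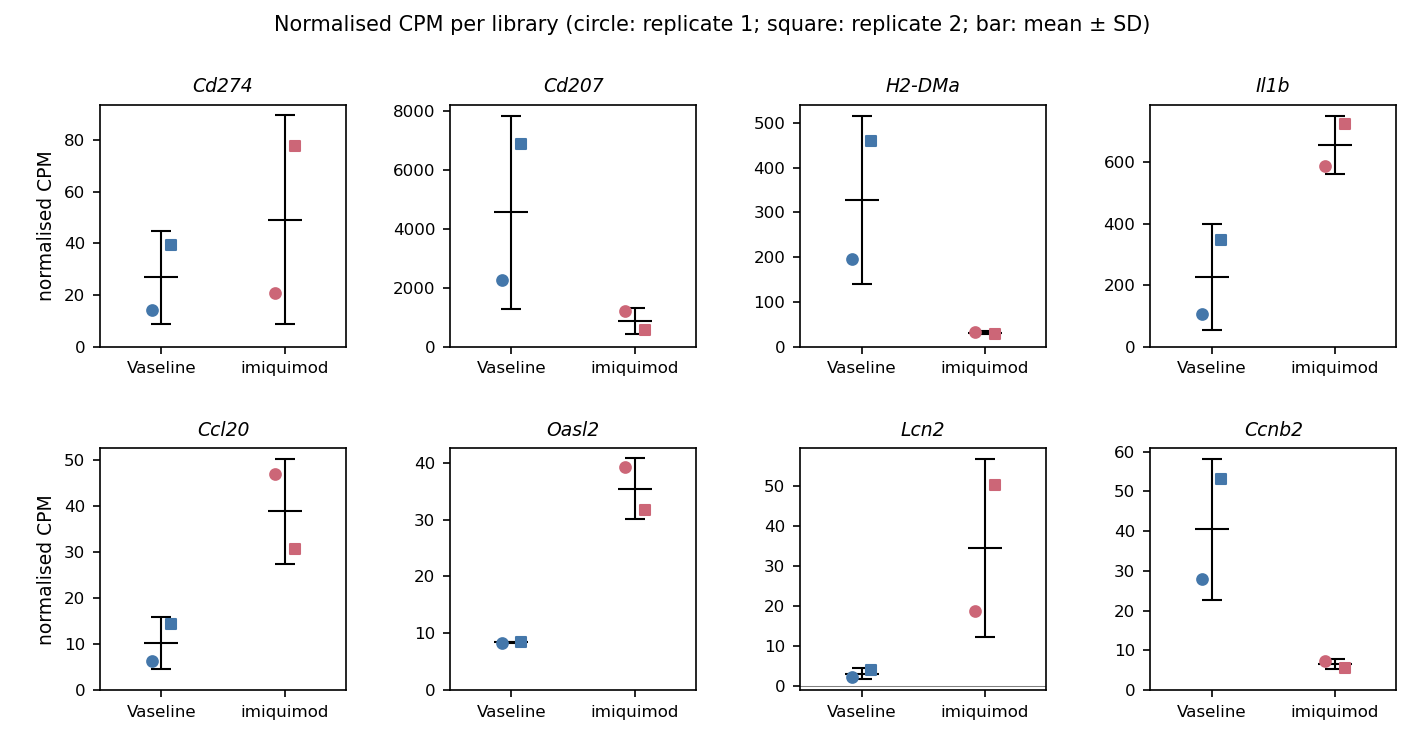
Normalised level (CPM) of Cd274, Cd207, H2-DMa, Il1b, Ccl20, Oasl2, Lcn2 and Ccnb2 in each library (circles, replicate 1; squares, replicate 2), with the mean and SD of each treatment (n = 2); Il1b was chosen after its values were seen. Groups overlap for Cd274, at 14.1 and 39.6 CPM with Vaseline and 20.6 and 77.7 with imiquimod, and are apart for the other genes.

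Each of the 34 cell cycle genes tested had a negative fold change. Of these, 2 fell over all genes, Bub1 (adjusted p = 0.0235) and Ccnb2 (adjusted p = 0.0332), and 24 adjusted over the list alone, among them Birc5 (-2.42), which acts in cell division, and Stmn1 (-2.77), which destabilises microtubules. The list passed with a median of -1.71 (adjusted p = 5.47e-27, and 0.604 with an estimated correlation). Among genes above background 33 of 34 were negative and 16 fell adjusted over the list alone, with a median of -0.92 (adjusted p = 3.57e-19, and 0.710 with an estimated correlation). Mitochondrially encoded transcripts, a mark of RNA quality, had -1.28 among all genes and -0.43 above background.

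Metabolic lists passed downward among all genes, each with adjusted p = 0.604 with an estimated correlation. Glycolysis and hypoxia genes (25 members, none past the threshold) had a median of -1.20, adjusted p = 2.76e-09, and the glycolytic enzymes Tpi1 and Eno1 had -1.85 and -1.79; above background the median was -0.40, adjusted p = 0.00665, and 0.919 with an estimated correlation. Their levels were -0.01 and 0.44 in Vaseline 1 and 2 and -0.38 and -0.14 in imiquimod 1 and 2. Respiratory chain genes (35 members) had -1.03, adjusted p = 2.64e-12, with Ndufa1 (-2.31) and Ndufa2 (-1.91) falling adjusted over the list alone; above background they had -0.28, adjusted p = 0.00163, and 0.919 with an estimated correlation. Their levels were 0.03 and 0.37 with Vaseline, 0.14 in imiquimod 1 and -0.56 in imiquimod 2 (log2, relative to the mean of the libraries). Ribosomal protein and basal keratinocyte genes were also low in imiquimod 2, at -0.96 and -0.91. Lipid handling genes (21 members) had -0.70, adjusted p = 0.000321, and the fatty acid receptor Cd36 (-2.14) and the desaturase Scd2 (-2.46) fell adjusted over the list alone; above background adjusted p = 0.106. Lysosome and phagocytosis genes (31 members) had -1.02, adjusted p = 1.09e-06, with 2 members falling, among them Hexa (-1.95), and the Fc receptor Fcgr4 (2.84) rising adjusted over the list alone; above background they had -0.25, adjusted p = 0.0485, and 0.902 with an estimated correlation, with levels of 0.04, 0.35, -0.22 and -0.21 in the libraries in that order. Cholesterol synthesis genes (23 members, none past the threshold) had -0.57, but 0.28 on library totals and 0.19 above background (adjusted p = 0.000859 among all genes and 0.355 above background). Antioxidant and stress response genes (22 members, none past the threshold) had -0.76, but 0.10 on library totals and 0.05 above background (adjusted p = 0.00346 and 0.513). In the last of these, Prdx1, a peroxide-reducing enzyme, had -1.46; without Vaseline 2 the preset calls of the cholesterol and antioxidant lists were lost, at adjusted p = 0.234 and 0.632, and without imiquimod 2 that of the antioxidant list, at 0.796.

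**Figure D4:**
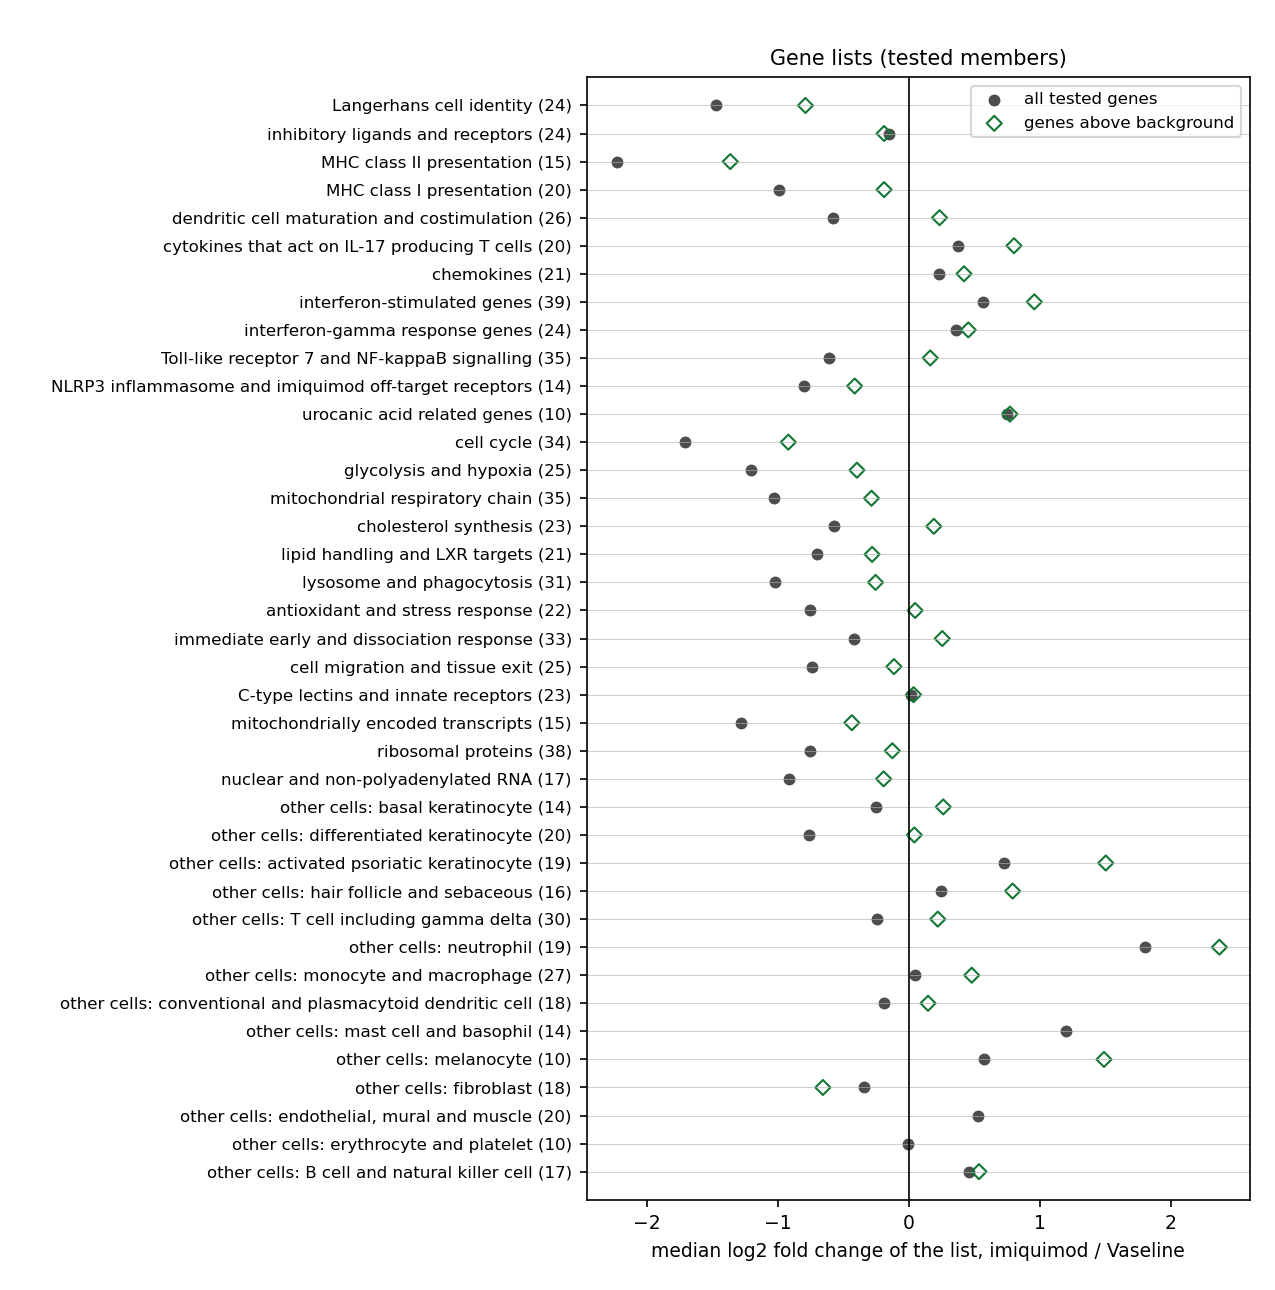
Median log2 fold change of the tested members of each list (number in parentheses) among all tested genes under TMM scaling (dots) and among genes above background (diamonds, shown where at least 3 members remain). Medians among all tested genes run from -2.23 for MHC class II presentation to 1.80 for neutrophil markers; several change sign between the fits, such as Toll-like receptor 7 and NF-kappaB signalling (-0.61 and 0.16).

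Among markers of other cells, those of neutrophils had the highest median, 1.80. Of 19 members tested, 4 rose and 1 fell over all genes, and 10 rose and 1 fell adjusted over the list alone. Lcn2, Mmp8, S100a8 and Hdc rose, while Mmp9, which other cells also make, fell. The list passed upward (adjusted p = 0.00348, and 0.604 with an estimated correlation), but not without Vaseline 1 (adjusted p = 0.177) or imiquimod 2 (0.426). It did not pass among the 8 members above background either (median 2.37, adjusted p = 0.106). Of these, the median level in imiquimod 2 was 1.71 (log2, relative to the mean of the libraries) and that in imiquimod 1 was -0.23. Mmp8 and Csf3r, both highest in imiquimod 2, fell below that bound at 4.36 and 4.55 times the background. Activated psoriatic keratinocyte genes passed upward (19 members; median 0.73, adjusted p = 0.0360 and 0.604 with an estimated correlation), with Lcn2 rising and Stfa3 falling over all genes, and 4 rising, among them the cornified envelope genes Sprr2d (2.20) and Sprr2h (2.02), and 1 falling adjusted over the list alone. With RLE factors that call was lost (adjusted p = 0.156), and without Vaseline 1 the test pointed down (0.711). Above background 9 of 15 rose and 1 fell adjusted over the list alone, with a median of 1.51 (adjusted p = 4.99e-10, and 0.710 with an estimated correlation).

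Basal keratinocyte genes passed downward (14 members, none past the threshold, median -0.25, but 0.03 with upper-quartile factors and 0.25 on library totals; adjusted p = 0.00392 and 0.604 with an estimated correlation). Their median level was 0.69 in imiquimod 1 and -0.91 in imiquimod 2, and without imiquimod 2 the test pointed up (adjusted p = 0.184); Krt5 had 3593 CPM in imiquimod 1 and 1160 in imiquimod 2. Above background their median was 0.26 and the test pointed down, adjusted p = 0.738. On library totals Krt14, a basal keratin, had 5305 and 4484 CPM in Vaseline 1 and 2 and 6829 and 2858 in imiquimod 1 and 2. Cd207 had 2151, 4113, 1262 and 952 in the same order. Krt14 thus exceeded Cd207 in each library, so list changes cannot be assigned to Langerhans cells alone. Differentiated keratinocyte genes passed downward (20 members; median -0.76, 0.16 on library totals; adjusted p = 0.00179 and 0.604 with an estimated correlation), with Krt77 (-3.58, adjusted p = 0.0415) falling over all genes and Cdsn (1.79) rising adjusted over the list alone. Above background they had 0.04 while the test pointed down, adjusted p = 0.893. Hair follicle and sebaceous genes did not pass (16 members, median 0.25 while the test pointed down, adjusted p = 0.351), though Krt79 (-2.48) and Postn (-2.83) fell adjusted over the list alone.

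T cell markers passed downward (30 members, none past the threshold, median -0.24, but 0.10 with upper-quartile factors, 0.59 on library totals and 0.22 above background; adjusted p = 0.0138 and 0.604 with an estimated correlation), with Cd2 at -1.83 and Cd3g at -1.68. Conventional and plasmacytoid dendritic cell markers passed downward (18 members, none past the threshold, median -0.19, but 0.16 with upper-quartile factors, 0.55 on library totals and 0.15 above background; adjusted p = 0.0116 and 0.604 with an estimated correlation), with Wdfy4 at -1.94. Above background neither passed (adjusted p = 0.386 and 0.827). Without Vaseline 2 both calls were lost (adjusted p = 0.0594 and 0.144), and without imiquimod 2 that of T cells (0.0954). Fibroblast markers passed downward (18 members; median -0.34, but 0.02 with upper-quartile factors and 0.59 on library totals; adjusted p = 0.00745 and 0.604 with an estimated correlation), with Col3a1 falling over all genes (-2.53, adjusted p = 0.0408); above background they had -0.66, adjusted p = 0.0478, and 0.902 with an estimated correlation. That call was lost without Vaseline 2 (0.167) or imiquimod 1 (0.224). Mast cell and basophil markers passed upward (14 members; median 1.20, adjusted p = 0.0377 and 0.604 with an estimated correlation), with Hdc alone rising; without Vaseline 1 or imiquimod 2 the call was lost (0.12 and 0.335). Above background 1 member had a positive fold change and 1 a negative, too few for a test. The olfactory and vomeronasal receptor genes had a median of 1.22 among all genes.

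Monocyte and macrophage markers did not pass (27 members; median 0.05, -0.20 with RLE factors and -0.25 with DESeq2, while the test pointed down; adjusted p = 0.287), with Fcgr4 (2.84) rising and Pf4 (-2.49) falling adjusted over the list alone; the list passed downward without Vaseline 1 (adjusted p = 0.0494) or imiquimod 2 (0.00155). Melanocyte markers did not pass (10 members, none past the threshold, median 0.58, adjusted p = 0.424), but did upward among the 3 members above background, where 2 rose adjusted over the list alone (median 1.49, adjusted p = 0.00900, and 0.710 with an estimated correlation). B cell and natural killer cell markers did not pass (17 members; median 0.46, adjusted p = 0.743), with Ighm falling over all genes and Ms4a1 (1.94) rising adjusted over the list alone. Endothelial, mural and muscle markers (20 members, none past the threshold; median 0.53, with 1 member positive and 1 negative above background; adjusted p = 0.177) and erythrocyte and platelet markers (10 members; median -0.01, 0.35 with upper-quartile factors; adjusted p = 0.521) did not pass; in the latter 1 member rose and Pf4 fell adjusted over the list alone.

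Lists chosen to show RNA quality and handling also differed. Mitochondrially encoded transcripts passed downward (15 members, none past the threshold, median -1.28, adjusted p = 2.17e-09 and 0.604 with an estimated correlation), with a level of -0.99 in imiquimod 1 and 0.09 in imiquimod 2; above background they had -0.43, adjusted p = 0.000521, and 0.902 with an estimated correlation. Ribosomal protein genes passed downward (38 members, none past the threshold, median -0.75, adjusted p = 2.05e-08 and 0.604 with an estimated correlation), with a level of 0.66 in imiquimod 1 and -0.96 in imiquimod 2, and without imiquimod 2 the call was lost (adjusted p = 0.951). Their median was -0.09 on library totals and -0.12 above background, where the list did not pass (adjusted p = 0.0508). Nuclear and non-polyadenylated RNA passed downward (17 members, median -0.92, adjusted p = 0.000127 and 0.604 with an estimated correlation), with 3 members falling adjusted over the list alone, among them the small RNA Rny3 (-2.48). The median was -0.12 on library totals and -0.19 above background, where the list did not pass (adjusted p = 0.398). Immediate early and dissociation response genes passed downward (33 members, none past the threshold, median -0.42, but 0.28 on library totals and 0.26 above background; adjusted p = 0.000427 and 0.604 with an estimated correlation, and 0.518 above background). Nr4a2, a nuclear receptor of that list, had -2.13. Without imiquimod 2 the test pointed up (adjusted p = 0.890) and without Vaseline 2 the call was lost (0.273). Protein-coding genes took 69.4% of counts in imiquimod 2 and 76.6% to 78.1% in the other libraries, and small RNA classes 16.1% against 9.11% to 10.7%.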

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

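Settings named here as protein-coding genes only, genes above background, subtraction of the background and the crossed block were chosen after seeing the data; the others were planned. No named gene past the threshold changed sign in any setting. With a simulated 8-fold change the quasi-likelihood fit recovered 15.6% of genes among all tested and 66.7% above background, so most changes of that size may stay uncalled in the first fit. Among genes above background 56 genes were called in the simulation and 0 in the data. The 66.7% therefore does not carry over to the data, and 0 calls there do not show that no gene changed.

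The numbers of genes higher and lower with imiquimod, 25 and 54, kept within 1.5 times with the robust quasi-likelihood form (23 and 67), summing genes that share a symbol (23 and 49) and leaving out markers of other cells (18 and 46). They were 17 and 14 with RLE factors, 41 and 56 with upper-quartile factors, 8 and 5 on library totals, 6 and 667 with DESeq2, 41 and 136 with limma-voom, 3 and 5 with the older quasi-likelihood form, 45 and 96 with the stricter filter, 66 and 128 at an adjusted p under 0.1, and 16 and 23 with a minimum fold of 1.5. Without the filter edgeR called 0 and 0, with 3185 and 1996 genes at an unadjusted p under 0.05. Leaving out single libraries gave 8 to 2959 genes higher and 0 to 317 lower, the extremes without imiquimod 2 and Vaseline 1. With a block for the replicate number they were 1 and 0 (1856 and 397 at an unadjusted p under 0.05). The deviations of same-numbered libraries correlated at -0.331, so pairing is not shown, and with the numbers crossed the block gave 0 and 0 (3420 and 4880 at an unadjusted p under 0.05). Protein-coding genes only gave 62 and 214. Genes above background gave 0 and 0 at 5 times (798 and 699 at an unadjusted p under 0.05) and 0 and 0 at 10 times (436 and 540), subtraction of the background 0 and 0 (2563 and 1477), DESeq2 on genes above background 97 and 156, and limma-voom 0 and 0 (913 and 634). Of the 25 and 54 genes, DESeq2 on genes above background called 8 and 38. The cause of these shifts was not tested beyond the tests on background given under other observations.

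The log2 fold change of Cd274, 0.89, did not pass in any setting and was positive in all but 1, up to 2.09 at 10 times background; leaving out single libraries gave -0.38 to 1.76, the lowest without imiquimod 2. The block for the replicate number gave 0.78.

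Of 39 lists, 28 passed by camera, 26 with ranked statistics, 27 with RLE factors and 28 with the block; leaving out single libraries gave 19 to 26. With an estimated correlation 0 passed and by fry 0, with protein-coding genes only 17, among genes above background 15, at 10 times 11, after subtraction 17, above background with an estimated correlation 0 and by fry 1, the melanocyte list. Lists that turned direction and passed in either setting are given by adjusted p; lists that passed in neither, such as 3 above background and 5 with protein-coding genes only, are not. Above background they were dendritic cell maturation (0.916), IL-17 cytokines (0.00745), Toll-like receptor 7 signalling (0.226), cholesterol synthesis (0.355), antioxidant (0.513), immediate early (0.518) and T cell (0.386). At 10 times background, in the same order, they had 0.573, 0.00685, 0.0122, 0.0886, 0.627, 0.0827 and 0.329, and basal and differentiated keratinocyte 0.847 each. After subtraction dendritic cell maturation had 0.902, IL-17 cytokines 0.0442 and immediate early 0.902. Above background with an estimated correlation, dendritic cell maturation had 0.965, Toll-like receptor 7 signalling 0.919, cholesterol synthesis, antioxidant and T cell 0.943 each, and immediate early 0.945. Above background by fry, dendritic cell maturation had 0.949, Toll-like receptor 7 signalling 0.732, cholesterol synthesis 0.739, antioxidant 0.841, immediate early 0.875, differentiated keratinocyte 0.949 and T cell 0.838. Leaving out single libraries gave 0.0334 to 0.915 for interferon-gamma response (turned without Vaseline 2, 0.0478), 4.52e-11 to 0.890 for immediate early and 8.92e-13 to 0.184 for basal keratinocyte (both turned without imiquimod 2), and 2.77e-08 to 0.711 for activated keratinocyte (turned without Vaseline 1). The cause of these turns was not tested.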

Other observations

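The tests in this part were chosen after the result was seen, except the comparison of gene families other than nasal receptors, and so were the genes named next. Among genes above background DESeq2 called 97 genes higher and 156 lower with imiquimod; 70 and 130 of them are on none of the fixed lists. All 97 and 156 had the same sign in the edgeR fit, and edgeR called 0 and 0 of these genes after adjustment, though 97 and 150 had an unadjusted p under 0.05 there. Fold changes and SEs of the genes named here and in the next paragraph are from that edgeR fit, unless stated. Among those higher and off the lists, Sprr2f and Sprr2e, cornified envelope proteins whose reads may be shared with paralogs, had log2 fold changes of 3.0 and 2.95, Gjb2, a connexin, 1.92 and Gsta4 1.82 (SE 0.36 and 0.34 for the last pair, n = 2 per group). Helz2, an interferon-induced helicase, had 1.83, the collagenase Mmp13 2.62 and Tnfsf18, the ligand of GITR, 2.25.

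Among those lower and off the lists, Hsd17b4 and Scp2, of peroxisomal fatty acid oxidation, had log2 fold changes of -2.31 and -2.21 (SE 0.34 and 0.35), Gm2a, a lysosomal activator of ganglioside breakdown, -2.02 and Nceh1, a cholesterol ester hydrolase, -1.77. The kinases Dmpk, Camk1d and Vrk1 had -2.37, -1.76 and -1.82, and Fam102b -1.83. Above background Hsd17b4 had an adjusted p of 0.312 by edgeR and 1.63e-06 by DESeq2. Scaled over all tested genes, it had 367 ± 154 CPM with Vaseline and 41.2 ± 1.42 with imiquimod (SD, n = 2 each). Its log2 fold change on that scale was -3.16 (edgeR adjusted p = 0.0963).

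Genes near the background had higher levels with imiquimod. The Vaseline libraries alone differed by 2.05 in log2 background, more than the group means (1.93), which argues against the treatment as the whole cause. Reads from no transcript, such as DNA, remain open: 98 genes of other families with no known role in skin lay -0.19, -0.04 and -0.14 (log2) from the nasal receptors in Vaseline 1, imiquimod 1 and imiquimod 2, but -1.32 in Vaseline 2. That crosses the bound of 1 set before the result was seen. By that bound alone the explanation would have counted as excluded. A bootstrap interval added afterwards had no finite lower end and reached 0.01, with 42.9% of those genes at a count of 0. Resampled medians can then fall to 0, so the interval is too wide to decide.

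The neutrophil list had a median log2 fold change of 1.80, but of 19 members tested only 4 rose and 1 fell over all genes. Above background its level in imiquimod 1 (-0.23) lay below that in Vaseline 2 (-0.06). Background reads are argued against as the whole cause. After their subtraction, with no filter, the 20 members rose by a median of 3.35 CPM per exonic kilobase (bootstrap interval over members 1.03 to 5.23). The 1768 nasal receptor genes had -0.01, but their own median was the value subtracted, so only their spread can serve as a comparison. Of the members, 13 rose by more than 1.40, the upper end of the central 95% of those genes, 5 lay within that range and 2 fell below it. If members varied like those genes, 0.5 would lie above. That spread is of nasal receptor genes, so it bears on background reads alone and not on whether the treatment raised the members. Neutrophils among the cells of imiquimod 2 stay open. After subtraction 16 members other than Lcn2, S100a8 and S100a9 were higher there than in imiquimod 1 by a median of 1.45, with 14 of them (87.5%) highest in that library. Nasal receptor genes, whose median was subtracted, had 0 and 40.6%. Only 5 of those members lay above background, with a median of 1.03 and 3 of them highest there. Mmp8 and Csf3r fell just under that bound (4.36 and 4.55 times), which gives libraries of low background most weight. On library totals they had 36.1 and 31.5 CPM in imiquimod 2 and 2.89 and 4.70 in imiquimod 1. Of the 20 members 5 are on another list. A sort for Langerhans cells, which the labels do not describe, would be meant to remove neutrophils. On library totals S100a9, an abundant neutrophil transcript, had 251 CPM in imiquimod 2 and 41.1 in imiquimod 1. For Lcn2, S100a8 and S100a9 in imiquimod 1, activated keratinocytes may be a source: their 14 other markers above background lay 0.91 above the higher Vaseline library. The 16 other neutrophil members tested lay 0.01 above it. These 16 include members near the background, such as Trem1 and Ltf at 1.39 and 1.60 times, so the values are not like for like.

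The Langerhans cell identity and MHC class II lists had negative medians with imiquimod, though no member of either passed over all genes. Neither list passed with an estimated correlation, and above background 6 of 22 identity genes were positive. For MHC class II, background reads and the scaling they pull are argued against, in these libraries only. Among genes above background the upper quartile was -0.88 (bootstrap interval up to -0.43), where the median of all those genes was 0.08. For the identity genes that explanation stays open, as their upper quartile was -0.0113 with an interval from -0.76 to 0.27. The interval was added to these tests after their values were seen, and without it the explanation would have counted as excluded. Both intervals resample genes and do not cover the spread between samples. The estimated correlation of class II genes was 0.914 among all tested genes. A lower share of Langerhans cells was tested only in the form where the other cells keep their proportions. In these libraries 2 lists of other cells did not move alike. Relative to the Vaseline mean, basal keratinocyte markers changed by 0.81 and -0.98 in imiquimod 1 and 2 and T cell markers by -0.17 and 0.28. The differences were 0.98 (bootstrap interval 0.32 to 1.38) and -1.26 (-1.54 to -0.87), where the Vaseline libraries differed by 0.15. These intervals resample marker genes within a library and do not cover the spread between samples. The estimated correlation of basal keratinocyte genes was 0.977 among all tested genes. The values speak against kept proportions in these imiquimod libraries, not against a lower share of Langerhans cells. A lower share with a change in single other cell types is not excluded: levels relative to the mean of the libraries, Vaseline 1 and 2 first, were 0.30, -0.22, 0.69 and -0.91 for basal keratinocyte, 0.17, -0.27, -0.13 and 0.22 for T cell and 0.14, 0.20, -0.14 and -0.12 for differentiated keratinocyte markers. The treatment itself remains among the open explanations.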
